A study of Mus musculus with 2 samples.

How the data were processed

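Cells positive for CD45 and CD90.2 were sorted from tumours of C57BL/6 mice, and 1 library per genotype label (WT and Dapl1-KO) was made with 10x Genomics 3′ chemistry, per the labels' protocols. The deposited values are whole-number UMI counts per gene and barcode for 32285 genes, with no normalization. The submitters' processing notes name Cell Ranger 5.0.0 and the genome builds mm10 and GRCm38, and the smallest barcode total in the count tables deposited by the authors was 500 UMIs in each library. How many animals or tumours went into each library is not given in the sources used here. Groups were taken from the genotype labels alone.

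Of the barcodes, 13132 occurred in both libraries. One copy was usually far smaller, with a median of 26.3% of the UMIs of the larger copy where the larger was in the library labelled WT and 10.8% where it was in the library labelled Dapl1-KO. The larger copy held 98.4% (median) of the smaller copy's gene counts, against 75.0% for barcodes paired at random. Only the larger copy was therefore kept, where it had at least 2 times the UMIs of the smaller, and 21 barcodes with no clear larger copy were left out. This removed 36.0% of barcodes in the library labelled WT and 36.4% in the library labelled Dapl1-KO, and departs from the design written beforehand, which kept all barcodes. The step was decided after the overlap had been seen and before expression was compared between the labels. The values with all deposited barcodes, which count both copies of each shared barcode, are given as an alternative.

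Cells with at least 500 genes and at most 10% mitochondrial counts were kept, which left 9865 and 11156 cells. The automatic threshold of the doublet caller Scrublet (in scanpy 1.11.5) called 0 cells, so a score limit was set for each library at a rate of 0.8% per 1000 cells (7.89% and 8.92% of cells). All cells at or above that score were removed, tied scores included, which took out 876 and 1006 cells (8.88% and 9.02%). Counts were scaled to 10000 per cell and log-transformed. Variable genes (2000, without T cell receptor variable segments, immunoglobulin, mitochondrial, ribosomal and sex-linked genes and Dapl1) gave 30 principal components, and a graph of 20 neighbours was clustered with the Leiden method at resolution 1. Clusters were named from 124 class markers fixed before the data were examined, by the mean log2 level of a class's markers over the median of all clusters, with a minimum of 0.5. At least 3 markers had to be detected in 10% of cells, and the CD8, CD4 and regulatory T classes also needed their lineage gene. The doublet rate, these naming rules and the copy rule were set after the data had been examined, when cells per library were visible, and clustering was run a second time under the final rules. A naming minimum of 0.3 was tried after cells per library had been seen. It made the finer clustering look closer to the main one, so the minimum of 0.5 was restored and 0.3 is reported as an added alternative. It renamed 0 cells in the main clustering. At resolution 2, the minimum of 0.5 left 12.9% of the cells in the library labelled WT and 14.4% in the library labelled Dapl1-KO unnamed, a cycling CD8-like cluster among them, against 1.45% and 1.52% with 0.3. Class names were rebuilt here and differ from any that the study used.

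Counts were summed per library and class and divided by the class total to give CPM. Class totals ran from 3881584 UMIs for CD4 conventional T-like cells to 85539011 for CD8-like cells. A log2 ratio sets the library labelled Dapl1-KO over the library labelled WT, with exact intervals from the counts, and a floor of 3 counts stands in for a count of 0. Named genes followed a rule fixed before the data were examined. In CD8-like cells they come from the 12 highest and 12 lowest ratios among genes at 50 CPM or more in a library, in the CD4, regulatory T and NK classes the 5 highest and 5 lowest, and up to 4 members of each fixed list with the largest ratios, along with a fixed set of checkpoint, progenitor and effector genes. Antigen receptor, haemoglobin, sex-linked, mitochondrial and ribosomal genes, unnamed gene models and lineage markers were left out of the ranking. Genes outside that rule that are named in the text were picked as list members after their values were seen, or are named as sex-linked genes, class markers or leading genes of clusters. Fixed gene lists (32) were summarised over members at 20 CPM or more in a library by the number at least 1.25-fold higher or lower, the median log2 ratio with an interval from 1000 Poisson draws, and the percentile of that median among 10000 random lists drawn within 20 expression bins. Lists with fewer than 3 measured members have no value here. Shares of cells have exact Clopper-Pearson intervals, and shares of cells with a UMI were taken after thinning each cell to 3000 UMIs. No test was run and no p-value is given, since each label has 1 library.

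The calculation was tested on simulated data for CD8-like cells: counts of 4405 genes, 200 of them changed by 1.5-fold or 2-fold. The intervals held the true ratio for 95.8% of genes, and 100% of the changed genes of either size and 0% of unchanged genes passed 1.25-fold. These simulations hold counting error only.

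Alternatives fixed before the data were examined were stricter cell filters (1000 genes and 5% mitochondrial counts), doublets kept, centring of genes within each library, resolution 2, a CD8 gate in place of clusters, cycling clusters left out, TMM factors (edgeR 4.0.16 in R 4.3.3) and median-of-ratios factors, the mean over cells, no minimum level for list members, and no thinning. Added afterwards were all deposited barcodes, the lower naming minimum, weighting to the WT cluster makeup, cells with Y-linked UMIs and no Xist, and the comparison of naive-like, monocyte- or macrophage-like, NKT-like and gamma-delta T-like shares. All alternatives for the type I interferon list and 16 further lists in CD8-like cells were added as well. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and gene positions came from the GENCODE M21 annotation of GRCm38. Intervals cover counting error only and are narrow because of depth, so they say nothing of differences between animals. Those of ratios and list medians also take each UMI as independent, without regard to how many cells gave the counts.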

Results

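The data comprised 2 single-cell RNA libraries of T cells and other lymphocytes sorted from tumours of C57BL/6 mice, an inbred laboratory strain. One library was labelled wild type (WT) and one was labelled as deficient for Dapl1 (Dapl1-KO). Sorted cells carried CD45, a marker of blood-derived cells, and CD90.2 (Thy1), a marker of T cells and some innate lymphocytes. The design asks how gene expression of T cells in tumours differs without Dapl1, and the study's subject is the function and exhaustion of CD8 T cells. Messages were counted as unique molecular identifiers (UMIs) from the 3′ ends of transcripts. The library labelled WT held 154408101 UMIs over 16673 barcodes and the library labelled Dapl1-KO held 206322042 UMIs over 19662 barcodes. After filtering, 8989 and 10150 cells remained, with medians of 7357 and 8488.5 UMIs and 1791 and 2019 genes per cell. With 1 library per genotype, no comparison below has a replicate check or a test. Intervals are exact 95% intervals for counts and shares, or Poisson draws for list medians, and cover counting error only, not differences between animals. Expression values are UMI counts summed over the cells of a class and scaled to the class total (CPM). Members of gene lists are counted as higher or lower only past the fold limit given with the methods.

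The targeted gene was measured first, since its level checks the labels. Dapl1 messages were not depleted in CD8-like or naive-like cells of the library labelled Dapl1-KO, against what its label would give if the counted 3′ ends were deleted. In CD8-like cells, Dapl1 had 521 counts in the library labelled WT and 1078 in the library labelled Dapl1-KO, or 8.43 and 12.6 CPM, a 1.49-fold higher level in the latter (log2 ratio 0.58, 0.43 to 0.73). Unthinned shares of cells with a Dapl1 UMI were higher there in the CD8-like clusters led by Ccl1 (4.25% and 5.61%) and Ifitm1 (4.33% and 6.26%). They were lower in those led by Gzmk (0.996% and 0.469%) and Gzmg (3.49% and 2.21%), and the intervals overlapped in each of these clusters. Naive-like T cells expressed Dapl1 most, with 2782 and 2073 counts, or 164 and 184 CPM (log2 ratio 0.17, 0.085 to 0.25). The share of naive-like cells with a Dapl1 UMI went the other way, at 26.8% and 23.8% after thinning and 35.0% and 31.6% without. These cells came mostly from different clusters in the 2 libraries. CD4 conventional T-like cells had 94 and 151 Dapl1 counts (log2 ratio 0.63, 0.25 to 1.02), and NKT-like cells had 45 and 69 (0.50, -0.063 to 1.07). In the opposite direction, regulatory T-like cells had 45 counts in the library labelled WT and 12 in the library labelled Dapl1-KO (log2 ratio -2.02, -3.07 to -1.07), and NK-like cells had 14 and 8 (-1.33, -2.79 to 0.023). Few cells held these counts, and the ratio intervals take each UMI as independent. The share of regulatory T-like cells with a Dapl1 UMI was 1.02% and 0.600% unthinned, and 0.281% and 0.411% after thinning. For NK-like cells it was 0.675% and 0.477% unthinned, and 0.695% and 0.0966% after thinning. The intervals of the 2 libraries overlapped for each of these shares. Over all kept cells the Dapl1 counts were 3582 and 3564, or 30.4 and 24.6 CPM (log2 ratio -0.31, -0.38 to -0.24), in libraries whose share of naive-like cells differed. Dapl1 (ENSMUSG00000026989) lies on the plus strand of mouse chromosome 2, from 59484653 to 59505020 in GRCm38. Its transcript has 4 exons, and the last, from 59504711 to 59505020, holds the 3′ untranslated region from 59504825 onwards. The position of the deletion is not given in the sources used here, and 3′ tags outside a deleted part say nothing about the genotype. The counts therefore neither bear out nor refute the labels, and both libraries are named by their labels throughout, with every direction below resting on those labels. The value for Dapl1 in CD8-like cells depended on how those cells were chosen. The log2 ratio was -0.44 when cells were gated on Cd8a or Cd8b1, Cd3 genes and no Cd4 or Foxp3 in place of clusters, a gate that took in naive-like cells (32.7% of gated cells in the library labelled WT and 15.7% in the library labelled Dapl1-KO). Under the other choices it ranged from 0.19 to 2.06.

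Sex-linked messages separated the libraries. Xist, the RNA that silences an X chromosome in female cells, was at 615 CPM in CD8-like cells of the library labelled WT and at 0.281 CPM in the library labelled Dapl1-KO. The Y-linked genes Ddx3y and Eif2s3y were at 6.50 and 17.5 CPM in the library labelled WT, against 43.1 and 80.5 CPM in the library labelled Dapl1-KO. Of the kept cells in the library labelled WT, 73.9% had Xist or Tsix without a Y-linked UMI and 10.9% had Y-linked UMIs without Xist or Tsix. In the library labelled Dapl1-KO these shares were 0.0887% and 69.6%. The genotype labels and the sex of most cells therefore coincide in every comparison below.

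CD8-like cells took a larger share of the library labelled Dapl1-KO, and naive-like T cells took a smaller one. CD8-like cells made up 31.6% (30.6 to 32.5) of kept cells in the library labelled WT and 43.5% (42.5 to 44.4) in the library labelled Dapl1-KO, a difference of 11.9 percentage points (10.5 to 13.3). Naive-like cells, with Ccr7, Lef1, Tcf7 and S1pr1 among their markers, made up 27.8% (26.8 to 28.7) and 13.2% (12.5 to 13.9). The naive-like class was chosen for comparison after its shares were seen. In its clusters, led by Gm26917, Klf2 and Fam241a, Cd8b1 had a UMI in 51.0%, 54.1% and 64.6% of cells and Cd4 in 3.96%, 11.4% and 2.34%. Many naive-like cells therefore expressed a CD8 gene. The larger CD8-like share does not by itself stand for a larger share of all CD8 T cells. NK-like cells made up 8.24% and 10.3%, a difference of 2.08 points (1.252 to 2.91). Regulatory T-like cells made up 13.1% of both libraries (difference 0.0170 points, -0.951 to 0.982), and CD4 conventional T-like cells 6.63% and 6.95% (0.315 points, -0.407 to 1.04). Monocyte- or macrophage-like cells made up 2.35% and 4.28%, NKT- or innate-like T cells 7.63% and 6.36%, and gamma-delta T-like cells 1.91% and 1.02%. One naive-like cluster of 2085 cells, 1707 of them from the library labelled WT, was led by Klf2, Dapl1 and Lef1 together with the heat-shock gene Hspa1a, so a trait of the library is not separated here from a cell type. Keeping every deposited barcode gave 0.755 points for the share of CD8-like cells, with an interval that included 0 (-0.429 to 1.94). The larger CD8-like share therefore depended on the barcodes kept. That setting counts both copies of each shared barcode, and the larger copy held 98.4% (median) of the smaller copy's gene counts. In the library labelled Dapl1-KO, Xist was found in 71.0% of smaller copies and 1.94% of larger ones. Counting a cell in both libraries can draw shares together, so the setting is no independent check, though the NK-like difference grew. This setting gave -6.33 points for the share of naive or central memory T-like cells and 3.18 for the share of NK-like cells. The same setting gave 1.31 points for the share of regulatory T-like cells and 1.65 for the share of CD4 conventional T-like cells. It turned the share of monocyte or macrophage-like cells to -0.546 points (3.85% and 3.30%), the share of NKT or innate-like T cells to 0.126 and the share of gamma-delta T-like cells to 0.0778, so the direction of these 3 differences depended on the barcodes kept. Stricter filters gave -3.49 points for NKT-like cells, and the CD8 gate (48.7% and 53.9% of kept cells) gave 5.16 points for CD8 cells.

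**Figure D1:**
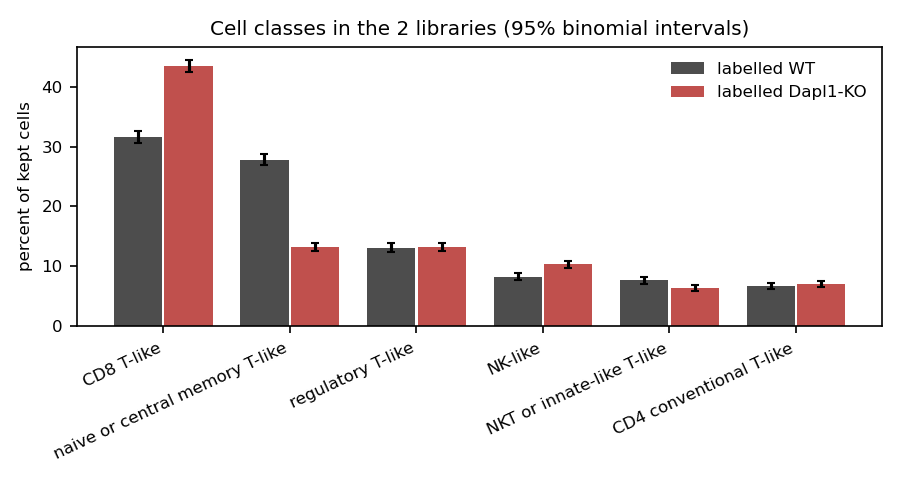
Percent of kept cells (vertical axis) in each of the 6 largest cell classes, with 1 bar per library and 95% exact binomial intervals as error bars. The CD8-like bar is at 31.6% for the library labelled WT and 43.5% for the library labelled Dapl1-KO, and the naive-like bar at 27.8% and 13.2%.

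Within CD8-like cells, Ifitm1, Areg, Ly6c2 and the cytotoxic genes Gzma, Gzmb and Prf1 were higher in the library labelled Dapl1-KO, and the heat-shock genes Hspa1a and Hspa1b, Ccr7 and the granzyme genes Gzmd, Gzme, Gzmf and Gzmg were lower. Ifitm1, an interferon-induced transmembrane protein, differed most, with 6.28 CPM in the library labelled WT and 67.1 CPM in the library labelled Dapl1-KO (10.7-fold; log2 ratio 3.42, 3.27 to 3.57). Areg, a growth factor of the EGF family, was 2.68-fold higher (1.42, 1.37 to 1.47), and Ly6c2, a surface marker of effector and memory T cells, 2.62-fold (1.39, 1.35 to 1.43). Klre1, a lectin-like receptor shared with NK cells, was 2.58-fold higher, and Gzma, a granule protease, 2.52-fold (log2 ratio 1.33, 1.30 to 1.37). Perforin (Prf1), which forms pores in target cells, was at 276 and 493 CPM (1.78-fold; log2 ratio 0.84, 0.81 to 0.86). The chemokine gene Ccl3 (1.95-fold), the nucleic acid sensor gene Zbp1 (1.97-fold), Lgals3 (1.91-fold), Mxd1 (1.83-fold) and Gng2 (1.81-fold) were also among the 12 highest genes. Among the 12 lowest, Hspa1a was 2.54-fold lower (log2 ratio -1.35, -1.38 to -1.31) and Hspa1b 2.14-fold, both inducible HSP70 chaperone genes. Gzmf, a granzyme gene of strongly activated T cells, was at 2922 and 1423 CPM (2.05-fold lower; log2 ratio -1.04, -1.05 to -1.03). Ccr7, the receptor that guides T cells to lymph nodes, was 2.02-fold lower (log2 ratio -1.01, -1.06 to -0.96), and Sytl3 2.03-fold. Lower levels were also measured for Snhg4 (1.99-fold), Penk (1.86-fold), Ddit4 (1.77-fold), Gstp1 (1.75-fold), Cd74 (1.73-fold), Tff1 (1.68-fold) and the histone gene Hist1h2ap (1.65-fold). No single cluster held most of the class. The one led by Gzmk, Ccl5 and Lag3 was the largest in the library labelled WT, while in the library labelled Dapl1-KO the one led by Ccl1, Nrgn and Gldc was close in size to one led by Ifitm1. The latter, with Gzma and Ly6c2 among its leading genes, is not compared in size between libraries, since these genes differed between the libraries. Of CD8-like cells, the one led by Gzmk held 31.9% (30.1 to 33.6) and 19.3% (18.2 to 20.5). The one led by Ccl1 held 22.4% and 25.1%, the cycling one led by Pclaf 21.5% and 23.0%, and the one led by Gzmg 8.07% and 6.16%. Each of these shares depends on the size of the cluster led by Ifitm1 as well. Ifitm1 and Ly6c2 were higher in the library labelled Dapl1-KO within each of the 5 larger CD8-like clusters (log2 ratios 2.38 to 4.35 and 0.73 to 1.73). By summed counts Gzma was not: it was lower in the cluster led by granzymes Gzmg and Gzmd (-0.73, -0.83 to -0.62) and near equal in the one led by Ccl1 (-0.069, -0.16 to 0.022). The share of cells with a Gzma UMI was nevertheless higher in the library labelled Dapl1-KO in both. After thinning it was 5.24% and 9.19% in the one led by Gzmg (18.8% and 33.1% unthinned). In the one led by Ccl1 it was 6.47% and 10.1% (17.2% and 28.0% unthinned). The cluster led by Gzmg and Gzmd held 143412 of the 180556 Gzmf counts of the library labelled WT, and Gzmf was lower there (-0.87, -0.88 to -0.86). In the cluster led by Gzmk it was higher in the library labelled Dapl1-KO (0.23, 0.029 to 0.42), as was Gzmg in the one led by Ccl1, with 30 and 122 counts (1.31, 0.72 to 1.93). The log2 ratio of Cd74 in CD8-like cells turned to 0.65 with the CD8 gate.

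**Figure D2:**
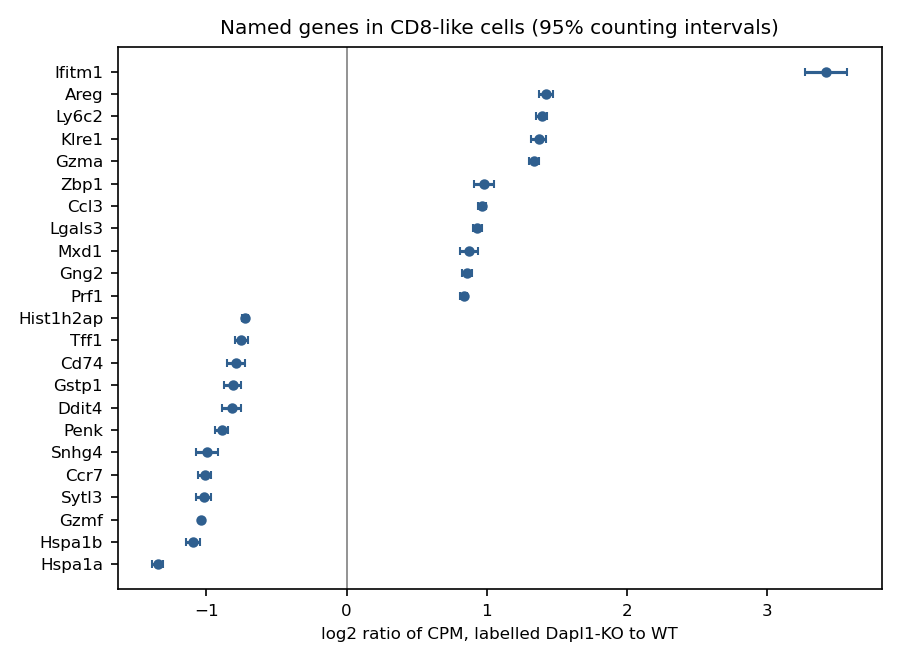
Log2 ratio of CPM in the library labelled Dapl1-KO to the library labelled WT (horizontal axis) for genes chosen by size in CD8-like cells, with 95% counting intervals as error bars. Ifitm1 stands at 3.42 and Hspa1a at -1.35, with the vertical line at 0 for equal levels.

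Among the lists fixed beforehand, most type I interferon genes were higher in CD8-like cells of the library labelled Dapl1-KO, while most proliferation genes were within the limit and cytotoxic genes were divided. Of 8 measured type I interferon response genes, 7 were higher and 0 lower (median log2 ratio 0.62, 0.58 to 0.65). In the 5 larger CD8-like clusters the median ran from 0.41 to 0.70, while in the smallest, led by Ifit3, Ifit1 and Isg15, 3 of 19 were higher and 8 lower (median -0.25, -0.45 to 0.028, with 22 cells in the library labelled WT). Examples were Isg15, a ubiquitin-like interferon-induced protein, at 11.5 and 29.6 CPM (2.57-fold), and Isg20 (1.65-fold). All 18 cytotoxic effector genes were measured, with 9 higher, 5 lower and a median of 0.25 (0.23 to 0.27). Gzmb was 1.53-fold higher and Nkg7, a granule membrane protein, 1.42-fold, while Gzmg was 1.58-fold lower and Gzmd 1.38-fold, so the granzyme family did not move as a whole. Of 23 proliferation genes, 10 were higher, 13 within the limit and 0 lower (median 0.29, 0.27 to 0.32), among them Rrm2, a subunit of ribonucleotide reductase (1.67-fold), Stmn1 (1.42-fold) and Top2a (1.39-fold), while Mki67 was at 153 and 171 CPM (1.12-fold). Among 10000 random lists of the same size and expression, the medians of these lists lay at percentiles 100, 99.9 and 100. The median of the proliferation list in CD8-like cells was 0.15 with all deposited barcodes kept and 0.68 among cells with Y-linked UMIs and no Xist. Between Y-linked and Xist cells within the library labelled WT it was -0.43 (-0.48 to -0.39). Such Y-linked cells numbered 389 of 2838 CD8-like cells in the library labelled WT and 3332 of 4413 in the library labelled Dapl1-KO.

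Of 16 measured exhaustion receptors and regulators, 3 were higher, 2 lower and 11 within the limit, with a median log2 ratio of -0.057 (-0.081 to -0.031; percentile 2.35). Inhibitory receptors were close in level: Pdcd1 (PD-1) was at 270 and 280 CPM, Havcr2 (TIM-3) at 96.8 and 91.0 CPM, and Lag3 at 223 and 219 CPM. Tox, a transcription factor of exhausted T cells, was at 142 and 130 CPM. Entpd1 (CD39) was at 35.2 and 52.9 CPM, Cd38 was 1.58-fold higher and Tnfrsf9 (4-1BB) 1.36-fold, while Eomes was 1.38-fold lower. Tigit, below the level for list members, was at 15.3 and 11.5 CPM. The exhaustion list in CD8-like cells turned to 0.054 with the CD8 gate, which took in unlike shares of naive-like cells (32.7% in the library labelled WT and 15.7% in the library labelled Dapl1-KO). Among cells with Y-linked UMIs and no Xist it was 0.049, with an interval that included 0 (-0.0036 to 0.13). The mean over cells and the setting without a member minimum moved it further down. Its direction was therefore not determined.

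Of 7 measured stem-like or progenitor genes, 2 were higher (Klf2, 1.37-fold, and Ly6c2, also a marker of effector and memory T cells) and 1 lower (Ccr7), with a median of 0.083 (0.050 to 0.13). Within clusters the median was -0.21 (-0.30 to -0.027) in the one led by Ccl1, -0.15 (-0.20 to -0.023) in the cycling one led by Pclaf and -0.88 (-1.03 to -0.23) in the smallest, led by Ifit3, and the intervals of the other 3 included 0, so the class median does not stand for its clusters. In the cluster led by Ccl1, Klf2 was lower (log2 ratio -0.23, -0.40 to -0.053). Tcf7 and Slamf6 were below the level for list members and are not among the 7 genes. Tcf7, the transcription factor of progenitor-like T cells, was at 11.9 and 12.6 CPM (log2 ratio 0.081, -0.056 to 0.22). Slamf6 was at 13.4 and 8.90 CPM, lower past the fold limit (log2 ratio -0.59, -0.73 to -0.44), and Il7r, a list member, was at 39.3 and 37.2 CPM. The median of the stem-like list in CD8-like cells turned to -0.69 with the CD8 gate, which took in naive-like cells. Among cells with Y-linked UMIs and no Xist it was -0.25 with members chosen anew, and -0.19 over the same 7 members, with an interval that included 0 (-0.33 to 0.021). For Klf2 in CD8-like cells these 2 settings gave -0.85 and -0.31. Among 8 effector cytokine and chemokine genes, Ifng was at 229 and 369 CPM (1.61-fold higher) and Ccl3 was higher, Il10 was 2.52-fold lower, and the median was 0.13 (0.11 to 0.16). That median was 0.024 (-0.022 to 0.067) in the cluster led by Gzmk, 0.21 (0.14 to 0.25) in the one led by Ccl1, 0.37 (0.24 to 0.50) in the one led by Ifitm1 and 1.18 (0.996 to 1.36) in the one led by Gzmg. It was -0.17 (-0.19 to -0.11) in the one led by Pclaf and -0.93 (-1.57 to -0.33) in the one led by Ifit3. In the cluster led by Gzmk, Ifng was level in summed counts (log2 ratio 0.018, -0.060 to 0.096). The share of cells with an Ifng UMI there was 42.9% and 48.0% after thinning, and 70.6% and 77.6% without. Tnf was at 9.16 and 9.56 CPM and Il2 at 1.34 and 1.19 CPM, ratios whose intervals included 0. The median of the cytokine list in CD8-like cells was -0.00029 with all deposited barcodes kept and -0.0087 without a minimum level for members, and it was 0.83 among cells with Y-linked UMIs and no Xist. Between Y-linked and Xist cells within the library labelled WT it was -0.39 (-0.53 to -0.34). Of 18 measured targets of NFAT, NF-kB and AP-1 after T cell receptor stimulation, 4 were higher (Egr1, Irf8, Fosb and Cd69), 3 lower (Nr4a1, Myc and Jun) and 11 within the limit (median 0.054, 0.032 to 0.077). Within clusters that median was 0.16 (0.077 to 0.21) in the one led by Gzmg, 0.15 (0.029 to 0.19) in the one led by Ifitm1 and 0.055 (0.020 to 0.098) in the one led by Pclaf. Its intervals included 0 in the ones led by Gzmk (-0.011), Ccl1 (-0.0042) and Ifit3 (-0.091). Jun was higher in the cluster led by Ifitm1 (0.26, 0.074 to 0.46). The transcription factors Nfatc1 (34.5 and 37.4 CPM) and Nfatc2 (5.86 and 6.73 CPM) were within the limit. Of 4 short-lived effector markers, Klre1 and Gzma were higher and none was lower (median 0.75, 0.71 to 0.79). The median was 0.87 (0.75 to 0.98) in the cluster led by Gzmk but 0.050 (-0.022 to 0.15) in the one led by Ccl1 and 0.11 (-0.019 to 0.25) in the one led by Gzmg. The short-lived effector markers list in CD8-like cells was at 1.28 among cells with Y-linked UMIs and no Xist and 0.43 with the CD8 gate, and within the library labelled WT it was lower in Y-linked than in Xist cells (-0.88, -1.04 to -0.73).

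**Figure D3:**
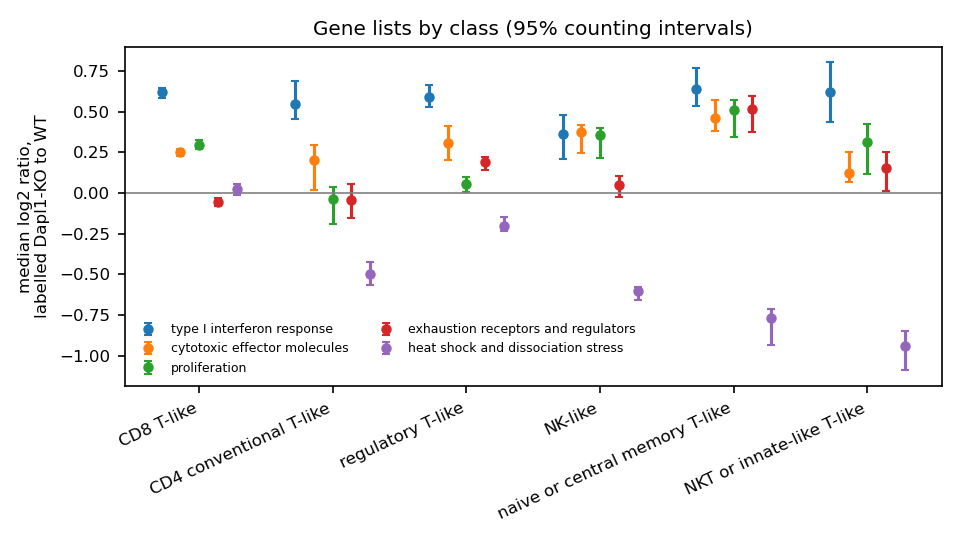
Median log2 ratio of 5 gene lists (vertical axis, the library labelled Dapl1-KO to the library labelled WT) in 6 cell classes, with 95% counting intervals as error bars. The type I interferon list lies above 0 in all 6 classes, from 0.36 in NK-like to 0.64 in naive-like cells, and the heat-shock list lies below 0 in the classes other than CD8-like cells. Within CD8-like cells (clusters not drawn) the heat-shock list was also lower in the clusters led by Ifitm1 (-0.27, -0.33 to -0.21) and Ifit3 (-0.36, -0.56 to -0.22). In the other CD8-like clusters it ran from -0.050 to 0.062.

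The share of CD8-like cells with both Pdcd1 and Havcr2 was close in the libraries, and the shares with a single receptor were not alike in the class and its clusters. After thinning each cell to 3000 UMIs, 11.9% of 2753 cells in the library labelled WT and 11.5% of 4290 in the library labelled Dapl1-KO had UMIs of both genes, a difference of -0.386 points (-1.96 to 1.16). Shallower cells, 85 and 123 in number, were left out. In the CD8-like cluster led by Gzmg and Gzmd the thinned shares with both genes were 11.4% (7.55 to 16.2) and 22.8% (17.9 to 28.2), and 92.1% and 95.6% unthinned. Over all CD8-like cells, thinned shares were 23.6% and 19.6% for Havcr2, 43.4% and 38.1% for Lag3, 34.8% and 29.6% for Tox, and 6.28% and 3.99% for Tigit, against 45.6% and 46.1% for Pdcd1 and 9.48% and 12.6% for Entpd1. Unthinned, they were 62.0% and 54.7% for Havcr2, 77.1% and 71.6% for Lag3, 75.3% and 65.8% for Tox, 26.1% and 18.3% for Tigit, 77.9% and 75.8% for Pdcd1, and 40.1% and 45.9% for Entpd1. Within clusters, thinned Lag3 shares were 51.7% and 50.4% in the one led by Gzmk (80.8% and 83.2% unthinned), 54.1% and 55.7% in the one led by Ccl1 (95.9% and 94.5%), 46.7% and 48.9% in the one led by Gzmg (98.7% and 98.2%), 9.32% and 10.1% in the one led by Ifitm1 (14.4% and 17.1%), and 40.1% and 38.4% in the cycling one led by Pclaf (92.0% and 90.9%). Havcr2 was found in a larger share in the one led by Gzmg (24.0% and 34.6%, or 93.4% and 97.1% unthinned). Its share was smaller in the ones led by Gzmk (25.9% and 22.7%, or 54.8% and 53.0% unthinned), Ccl1 (29.2% and 27.1%, or 79.7% and 74.6%) and Ifitm1 (6.03% and 4.69%, or 10.0% and 8.56%). The intervals of the Havcr2 shares overlapped in each of these clusters, the one led by Gzmg included, thinned or not. Pdcd1 was at 47.4% and 57.7% in the one led by Gzmk (79.5% and 85.2% unthinned), 48.9% and 54.9% in the one led by Ccl1 (88.2% and 92.0%) and 49.3% and 61.4% in the one led by Gzmg (98.3% and 98.2%). In the one led by Ifitm1, Pdcd1 was at 23.6% and 21.8% (31.9% and 31.0% unthinned). The class values therefore do not stand for each cluster. The cluster led by Gzmk, where Lag3 was found in a larger share than in the class, held 31.9% and 19.3% of CD8-like cells. How much of the class differences in these shares follows from cluster makeup was not tested. In naive-like cells the thinned shares were 1.42% and 1.89% for Havcr2, 2.42% and 5.01% for Lag3, 12.2% and 8.96% for Tox, 0.734% and 0.904% for Tigit, 3.80% and 5.75% for Pdcd1, and 0.432% and 1.23% for Entpd1. Without thinning the shares with both Pdcd1 and Havcr2 were 55.4% and 50.5%, a difference of -4.96 points, at median depths of 14783 and 13589 UMIs. As background, 0.173% and 1.40% of naive-like cells had both genes after thinning, at median depths of 6042 and 7926 UMIs, and 0 of 719 and 0 of 1035 NK-like cells did, at 6200 and 6707 UMIs. With the CD8 gate the share of CD8-like cells with Pdcd1 and Havcr2 differed by 1.47 points in the other direction, in a population with a different content of naive-like cells.

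In CD4 conventional T-like cells, interferon-induced genes and Il13 were higher in the library labelled Dapl1-KO, and heat-shock genes, Il17a, Tmem176a and Tmem176b were lower. Il13, a cytokine of type 2 helper cells, had 11 counts in the library labelled WT and 214 in the library labelled Dapl1-KO (18.7-fold; log2 ratio 4.23, 3.36 to 5.25). The interval takes each UMI as independent, and how many cells held these Il13 counts is not given here, so they may come from few cells. Il10 (2.47-fold), Serpinb1a (2.47-fold), Ifitm3 (2.47-fold) and Isg15 (2.43-fold) followed. Lowest were Tff1 (5.08-fold lower), the metallothionein gene Mt2 (3.56-fold), the decoy interleukin-1 receptor gene Il1r2 (3.40-fold), Ramp1 (3.24-fold) and Penk (3.06-fold). Of 10 type I interferon genes 8 were higher and 0 lower (median 0.55, 0.45 to 0.69), as were 9 of 17 interferon-gamma and MHC class I genes (median 0.35, 0.26 to 0.39), among them Gbp2. Of 17 heat-shock genes 11 were lower and 1, Egr1, higher (median -0.50, -0.57 to -0.43), with Hspa1a at 2420 and 836 CPM. Of 4 type 17 genes, 3 were lower, namely Il17a (81.9 and 49.4 CPM), Tmem176a and Tmem176b, and S100a4 was higher (median -1.06, -1.19 to -0.85). Free RNA in droplets was not removed, the cluster of gamma-delta T-like cells led by Il17a held 1.91% and 1.02% of cells, and Tmem176a and Tmem176b were lower in NK-like cells too (type 17 median -0.91, -1.12 to -0.66). Of 4 type 2 genes, Il13 and Areg were higher and Ccr8 was lower (median 0.39, 0.21 to 0.56). These sums rest on 596 and 705 cells, and the directions rest on labels that the Dapl1 counts did not bear out.

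Regulatory T-like cells also had higher interferon-induced genes in the library labelled Dapl1-KO. All 10 measured type I interferon genes were higher (median 0.59, 0.53 to 0.66), among them Isg15 (2.01-fold). Spp1, which encodes osteopontin and is abundant in macrophages, was at 11.4 and 62.2 CPM (5.46-fold; log2 ratio 2.45, 2.21 to 2.69). The chemokine genes Ccl4 (2.53-fold) and Ccl3 (2.07-fold) and the granule gene Nkg7 (689 and 1374 CPM) were higher too, all of them genes that CD8-like or myeloid cells express. Lower levels were measured for Hspa1a (2.58-fold), Hspa1b (2.53-fold), Emb (1.83-fold), Gstp1 (1.80-fold) and Rgs1 (1.74-fold). Of 19 regulatory T cell effector genes, 3 were higher and 4 lower (median 0.11, 0.048 to 0.19), with Areg at 273 and 534 CPM and Il10 at 90.0 and 54.7 CPM. Free RNA in droplets was not removed, and Cd8b1 had a UMI in 21.4% of cells of the larger regulatory T-like cluster.

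NK-like cells of the library labelled Dapl1-KO had higher Gzma, Gzmb and Prf1 and much lower heat-shock genes. Pmepa1, a target of TGF-beta signalling, was 2.28-fold higher (log2 ratio 1.19, 0.99 to 1.39), followed by the integrin gene Itgb2 (2.08-fold), the receptor gene Klra3 (2.03-fold), Crem (1.99-fold) and Tubb4b (1.88-fold). Hspa1a was at 1993 and 282 CPM (7.06-fold lower; log2 ratio -2.82, -2.88 to -2.75), and Hspa1b (5.83-fold), Hspb1 (5.45-fold) and Dnajb1 (4.12-fold) were lower with it. The chemokine gene Ccl1 was 4.28-fold lower. Of 16 measured cytotoxic genes 9 were higher and 3 lower (median 0.38, 0.25 to 0.42), with Gzma at 3926 and 7327 CPM and Gzmb at 593 and 923 CPM. Of 8 short-lived effector markers 5 were higher and 1 lower (median 0.83, 0.62 to 0.85), and of 9 type I interferon genes 5 were higher and 0 lower (median 0.36, 0.21 to 0.48). Il7r, the interleukin-7 receptor gene, was at 111 and 38.5 CPM. The sums rest on 741 and 1048 NK-like cells, and the heat-shock difference moves with the library in this class as in the CD4 and naive-like classes.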

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

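The tests on shared barcodes were chosen after the overlap had been seen. Smaller copies of barcodes found in both libraries held 9.31% of the UMIs in the library labelled WT and 15.3% in the library labelled Dapl1-KO, a signal in data that the comparisons leave out. Molecules of one library read into the other are a candidate explanation. Xist was present in 71.0% of the smaller copies in the library labelled Dapl1-KO, against 1.94% of its larger copies, as such reads would give. Separate droplets that drew the same barcode by chance would share no more than random pairs (75.0% in the median, 92.4% at the 95th percentile), while the median overlap of gene counts was 98.4%. The step at which this arose was not tested.

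Melanocytic tumour-like cells, led by Dct, Tyrp1 and Pmel, numbered 25 in the library labelled WT and 58 in the library labelled Dapl1-KO, a signal in cells outside the comparisons and outside the sorted markers. The numbers were 40 and 50 under stricter filters and 54 and 64 with all deposited barcodes. Under stricter filters no fibroblast-like class was named, against 23 and 7 such cells in the main setting. The class median in the library labelled WT was 62794 UMIs there and 19624 with all deposited barcodes, against 137628 in the main setting. The class thus held different barcodes in these settings, which do not show whether the imbalance holds. In the main setting the median of melanocytic-like cells was 129553 UMIs per barcode, and 51.8% of them had a Cd3e UMI. Whether they are tumour cells or multiplets was not tested.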

How the results depend on the processing

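Of the alternatives, all deposited barcodes, the lower naming minimum, the WT cluster makeup and cells with Y-linked UMIs, and each alternative for the naive-like, monocyte- or macrophage-like, NKT-like and gamma-delta T-like shares, for the type I interferon list and for 16 further lists, were chosen after the data were seen. Intervals cover counting error and are narrow at these depths, so small shifts leave them. Classes with fewer UMIs (3881584 in CD4 conventional T-like cells of the library labelled WT) carry wider ones. Where a value below differs, the cause was not tested. Gene and list results in classes other than CD8-like cells were not recomputed under the alternatives. Of 118 single genes in CD8-like cells, 106 stayed within their counting interval under stricter filters, 85 with doublets kept, 99 with centring, 65 at resolution 2, 114 with the lower naming minimum, 72 with TMM factors and 59 with median-of-ratios factors. In these settings the others moved, with no reversal among genes past the fold limit. The numbers within the interval were 66 without cycling clusters, 47 with the mean over cells (1 reversed), 48 with the WT cluster makeup (1 reversed), 29 with the CD8 gate (4 reversed), 27 of 118 with all deposited barcodes, and 17 of 114 with Y-linked cells (4 reversed).

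Dapl1 in CD8-like cells (log2 ratio 0.58) was 0.39 under stricter filters, 0.19 with centring, 1.27 at resolution 2, 0.93 without cycling clusters, 0.97 as the mean over cells, 2.06 in Y-linked cells and reversed to -0.44 with the CD8 gate.

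The share of CD8-like cells (difference 11.9 points) was 10.1 with centring, 8.20 at resolution 2, 5.16 with the CD8 gate and 0.755 (-0.429 to 1.94) with all deposited barcodes. The share of naive or central memory T-like cells (-14.6) was -13.0 under stricter filters, -12.7 with centring and -6.33 with all deposited barcodes. The share of CD4 conventional T-like cells (0.315) was 1.496 with centring, 1.88 at resolution 2 with either naming minimum and 1.65 with all deposited barcodes. With all deposited barcodes, the share of regulatory T-like cells (0.0170) was 1.31 and the share of NK-like cells (2.08) was 3.18, and 3 shares reversed: the share of monocyte or macrophage-like cells (1.93) to -0.546, the share of NKT or innate-like T cells (-1.27) to 0.126 and the share of gamma-delta T-like cells (-0.889) to 0.0778. With doublets kept the share of monocyte or macrophage-like cells was 2.61, and the share of NKT or innate-like T cells was -3.49 under stricter filters and -2.44 with centring. The share of CD8-like cells with Pdcd1 and Havcr2 (-0.386) was 1.47 with the CD8 gate and -4.96 without thinning.

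The exhaustion list in CD8-like cells (-0.057) was -0.030 at resolution 2, -0.016 with TMM factors, -0.0033 with median-of-ratios factors, -0.16 as the mean over cells and -0.090 without a member minimum, and reversed to 0.054 with the CD8 gate and 0.049 (-0.0036 to 0.13) in Y-linked cells. The stem-like list in CD8-like cells (0.083) was 0.28 at resolution 2, 0.13 with the lower naming minimum, 0.27 without cycling clusters, 0.0092 with all deposited barcodes, 0.14 with median-of-ratios factors, 0.19 as the mean over cells and 0.0015 with the WT cluster makeup, and reversed to -0.69 with the CD8 gate and -0.25 in Y-linked cells with members chosen anew (-0.19, -0.33 to 0.021, over the same members).

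The cytotoxic list in CD8-like cells (0.25) was 0.22 with doublets kept, 0.23 at resolution 2, 0.32 with the CD8 gate, 0.22 without cycling clusters, 0.19 in Y-linked cells, 0.20 with all deposited barcodes, 0.29 with TMM factors, 0.31 with median-of-ratios factors, 0.20 as the mean over cells and 0.28 with the WT cluster makeup. The proliferation list in CD8-like cells (0.29) was 0.34 with doublets kept, 0.33 with centring, 0.27 at resolution 2, 0.43 with the CD8 gate, 0.68 in Y-linked cells, 0.15 with all deposited barcodes, 0.34 with TMM factors, 0.35 with median-of-ratios factors and 0.32 as the mean over cells.

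The cytokine list in CD8-like cells (0.13) was 0.16 under stricter filters, 0.48 at resolution 2, 0.17 with the lower naming minimum, 0.17 with the CD8 gate, 0.33 without cycling clusters, 0.83 in Y-linked cells, 0.17 with TMM factors, 0.18 with median-of-ratios factors, 0.061 as the mean over cells and 0.025 with the WT cluster makeup, and reversed to -0.00029 with all deposited barcodes and -0.0087 without a member minimum. The TCR-induced list in CD8-like cells (0.054) was 0.085 at resolution 2, 0.0060 with the CD8 gate, 0.12 in Y-linked cells, 0.096 with TMM factors and 0.11 with median-of-ratios factors.

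The type I interferon list in CD8-like cells (0.62) was 0.65 under stricter filters, 0.67 with doublets kept, 0.65 at resolution 2, 0.67 with the CD8 gate, 0.58 without cycling clusters, 0.88 in Y-linked cells, 0.50 with all deposited barcodes, 0.67 with TMM factors, 0.68 with median-of-ratios factors, 0.66 as the mean over cells and 0.72 without a member minimum. Of 16 other lists in CD8-like cells, 14 stayed within their counting interval under stricter filters, 9 with doublets kept, 16 with centring, 5 at resolution 2, 14 with the lower naming minimum, 1 with the CD8 gate, 7 without cycling clusters, 4 in Y-linked cells, 7 with all deposited barcodes, 4 with TMM factors, 2 with median-of-ratios factors, 7 as the mean over cells, 6 with the WT cluster makeup and 10 without a member minimum. Of these lists, 4 reversed: the tissue-residency markers list in CD8-like cells (0.083) to -0.0048 with the CD8 gate, the apoptosis regulators list in CD8-like cells (-0.11) to 0.055 without cycling clusters, and, in Y-linked cells, the TGF-beta response list in CD8-like cells (0.14) to -0.13 with members chosen anew (-0.0070, -0.085 to 0.087, over the same members) and the cholesterol synthesis list in CD8-like cells (-0.11) to 0.36. The hypoxia, heat-shock and macrophage lists, with intervals that included 0, took either sign.

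Single genes reversed as follows. With the CD8 gate, Cd69 in CD8-like cells was -0.13, Cd74 in CD8-like cells 0.65, Klf2 in CD8-like cells -0.85 and Hsph1 in CD8-like cells -0.030. Hsph1 was also -0.069 as the mean over cells and -0.014 with the WT cluster makeup. In Y-linked cells, Klf2 was -0.31, Hmgcs1 in CD8-like cells 0.37, Myc in CD8-like cells 0.26 and Sqle in CD8-like cells 0.11.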

Other observations

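Naive-like T cells, a class chosen after its values were seen, had lower heat-shock genes and higher respiratory and cytotoxic genes in the library labelled Dapl1-KO. Of 17 heat-shock and dissociation genes 15 were lower and 0 higher (median log2 ratio -0.77, -0.93 to -0.71), with Hspa1a at 2019 and 227 CPM and the co-chaperone gene Dnajb1 at 739 and 175 CPM. Of 23 genes of oxidative phosphorylation 18 were higher and 0 lower (median 0.57, 0.50 to 0.59), among them Cox5a and Ndufa4. Of 12 cytotoxic genes 9 were higher and 0 lower (median 0.46, 0.38 to 0.57), among them Gzmb (2.72-fold), Ccl5, Nkg7 and Prf1, all genes that CD8-like cells express, and free RNA in droplets was not removed. The chemokine gene Xcl1 was 3.15-fold higher and Ly6c2 2.42-fold. Of 9 type I interferon genes 7 were higher and 0 lower (median 0.64, 0.54 to 0.77). Naive-like cells came mostly from different clusters: the cluster led by Klf2 with Hspa1a among its leading genes in the library labelled WT, and one led by Fam241a, Dapl1 and Tmem108 in the library labelled Dapl1-KO.

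NKT-like cells also had lower heat-shock genes in the library labelled Dapl1-KO, 16 of 17 (median -0.94, -1.09 to -0.85), with Hspa1a at 3226 and 478 CPM. In CD8-like cells, 5 of 11 genes of the unfolded protein response were higher and 1 lower (median 0.26, 0.23 to 0.29), among them the chaperone genes Hsp90b1 and Calr. That median was 0.70 (0.64 to 0.77) among cells with Y-linked UMIs and no Xist, and -0.45 (-0.54 to -0.31) between Y-linked and Xist cells within the library labelled WT. All 24 ribosomal protein genes measured there were within the fold limit, with a median of -0.17 (-0.17 to -0.16), and 2 of 8 genes of cholesterol synthesis, Hmgcs1 and Sqle, were lower and 0 higher (median -0.11, -0.17 to -0.084). The direction of the cholesterol list was not determined: over the same members the median was 0.36 (0.27 to 0.44) among cells with Y-linked UMIs and no Xist, and 0.15 (0.068 to 0.21) in the cluster led by Ccl1. Between Y-linked and Xist cells within the library labelled WT it was -0.54 (-0.64 to -0.47).

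Of the tests below, those on Dapl1 were chosen after its counts had been seen. Predictions for the tests on the interferon genes were written before the values of those tests were seen. They already named the list as higher in the library labelled Dapl1-KO, and the settings they use were chosen after the data were seen. Dapl1 counts in the library labelled Dapl1-KO have 3 candidate explanations. Molecules of the WT library counted in the other would carry Xist along, yet Xist in naive-like cells was at 0.0202% of its level in the library labelled WT while Dapl1 was at 112%. Tags outside the deleted part would give counts near the WT level, as that 112% is, but without the position of the deletion no bound can be set. Exchanged labels would put Dapl1 lower in the library labelled WT, and its CPM was lower there in the 4 classes with at least 100 counts (log2 ratio 0.17 in naive-like cells, with an interval that included 0 in NKT-like cells), but not in regulatory T-like cells with 57 counts. Those 57 counts came from 1.02% and 0.600% of regulatory T-like cells, with overlapping intervals, so that class decides little. Against the CPM, the share of naive-like cells with a Dapl1 UMI was higher in the library labelled WT (26.8% and 23.8% after thinning, 35.0% and 31.6% without). Naive-like cells also came mostly from different clusters in the 2 libraries. A further requirement of a 10-fold difference in CPM, set after the CPM values were seen, was not met, so both of the last 2 explanations stay open.

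The type I interferon list was higher by a median of 0.62 in CD8-like cells of the library labelled Dapl1-KO. Sex of the animals could account for this if cells with Y-linked UMIs were higher within the library labelled WT, but they were lower than its cells with Xist (median -0.25, -0.38 to -0.16). These Y-linked cells may come from another animal, so this test is not clean. A different makeup of CD8-like clusters would bring the median near 0 at the WT makeup, and it was 0.63. Library handling, differences between animals and genotype were not told apart by either test, and all stay open.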
